A study of Rattus norvegicus with 4 samples.

How the data were processed

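Hdac3 and p300 were each immunoprecipitated from rat OPCs and from differentiating oligodendrocytes (d3), which gave 4 libraries, 1 per group. Per the labels' protocols, the precursors came from the cortex of pups at postnatal day 2 and were separated by differential detachment. The growth medium held the mitogens PDGF-AA at 10 ng/ml and bFGF at 20 ng/ml. The differentiation medium held thyroid hormone (T3) at 15 nM and ciliary neurotrophic factor at 10 ng/ml. The labels name the antibodies (Abcam for Hdac3, Santa Cruz for p300) and a SOLiD fragment library kit. The groups were taken from the sample titles. What d3 stands for beyond the title and the cell type label, read here as day 3, is not given in the sources used here.

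The deposited files are lists of aligned reads in rn4 coordinates on chromosomes 1 to 20, X and M, with a start, an end, a strand and a score for each read. Build rn4 and MACS 1.4.0 are named in the submitters' processing notes, without their roles. The aligner, the read filters and any pooling of samples are not given in the sources used here. The score deposited by the authors for each read is a whole number from 8 to 100. Its scale is undocumented, and it was read as a mapping quality. Between 63.3% and 68.1% of reads in a library had a score of 100. Most reads were 35 bp long, in a range of 25 to 54 bp. In each library no 5' end occurred more than 1 time on the same strand, so repeated reads had been removed before deposition and the rate of duplication cannot be given. Removal of repeats caps the tags a narrow site can hold.

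Tags on the 21 assembled chromosomes (20 autosomes and X) were moved 100 bp in their own direction and counted in 1 kb bins, 2718850 in all. For calling, the libraries were thinned at random (seed 1) to the smallest, 3488532 tags. A bin was called enriched where the Poisson upper tail was below 1e-05 and the count was at least 3-fold over background. Background was the highest of the genome mean, the mean of the surrounding 10 kb and that of the surrounding 50 kb, with the bin itself left out. Adjacent called bins were merged. The Poisson level served as a calling rule within a library and not as a test between conditions. Fold over background and depth-scaled tags (RPM) were computed from the full libraries.

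Ratios between libraries were computed from tag counts scaled by the total on assembled chromosomes, with exact conditional binomial 95% intervals. Shares have exact Clopper-Pearson intervals. Medians, strand offsets and summed folds have bootstrap intervals from 1000 draws. Overlap was at least 1 bp, beside 100 random placements on the same chromosome. For log2 ratios a pseudocount of 0.5 was used. All intervals cover counting error or the spread over regions, and not the spread between cultures, because each group held 1 library. No test between conditions was made for the same reason. No input library was used here, so sites that collect reads in any library could not be subtracted.

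The named regions followed a rule written before the data were examined, as did the comparisons and most of the other settings tried. The rule took, for each library, the 5 regions of highest fold, the 5 regions called in all 4 libraries with the highest mean fold, and for each protein the 5 largest increases and decreases among called regions with at least 50 tags over its libraries. Comparisons added after the data were examined were the well-placed regions (mean read score of at least 80), the ratio of Hdac3 to p300 in each region, windows of 500 kb, 1 Mb and 5 Mb, and strand offsets. Fixed gene lists and promoter counts were not run, because the gene table at hand describes another assembly than rn4 and its positions were not used here.

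The calling rule was tested on simulated data with Poisson background taken from each library's local means at equal depth and 200 planted bins, over 2718850 bins. For Hdac3 in OPCs it recovered 28% of bins planted at 5-fold, 80% at 10-fold and 100% at 20-fold, with 10 false bins. For Hdac3 at d3 the recovery was 22%, 84% and 100%, with 8 false bins. For p300 in OPCs it was 10%, 70% and 100%, with 8 false bins, and for p300 at d3 14%, 84% and 100%, also with 8 false bins. The simulated background followed 50 kb means with counting error alone. It held no sites that collect reads in any library, so the false bins give no error rate for the real calls. The interval of the ratio was tested over 1874 bins with no true change and excluded 1 in 3.26% of them for Hdac3 and 2.45% for p300. At a true ratio of 2 it excluded 1 in 29.2% and 17.6% of bins, so changes of that size were mostly beyond the depth of single bins. This simulation split each bin's tags at random, so it covers neither the picking of regions by a call nor spread beyond counting error.

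Alternatives were all tags kept, 500 bp bins, a Poisson level of 1e-08, no thinning, overlap of 50% of the shorter region, leaving out bins over 10 times the mean of every library, scaling by tags outside called regions and, added later, a second thinning seed, reads with a score of at least 50, the genome mean as the only background, and regions with a mean score of at least 80. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.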

Results

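The data were 4 chromatin immunoprecipitation sequencing (ChIP-seq) libraries from primary rat oligodendrocyte precursor cells (OPCs), the proliferating cells that give rise to myelin-forming oligodendrocytes. OPCs were taken from the cortices of Sprague Dawley pups at postnatal day 2. One set of libraries came from OPCs and the other from differentiating oligodendrocytes, labelled d3. At each stage 1 library was made with an antibody to Hdac3, a histone deacetylase that acts in corepressor complexes, and 1 with an antibody to p300, a histone acetyltransferase often found at active enhancers. Each group therefore held 1 library, no input library was used here, and no difference between stages or antibodies could be set against a spread between replicates. The 95% intervals given below cover counting error, or for medians, strand offsets and summed folds the spread over regions, and never the spread between cultures. The deposited reads on assembled chromosomes numbered 4337338 for Hdac3 in OPCs, 8916784 for Hdac3 at d3, 3488532 for p300 in OPCs and 4712200 for p300 at d3. The average 1 kb bin of the rn4 genome accordingly held 1.60, 3.28, 1.28 and 1.73 tags. Gene positions in rn4 were not used here, so regions are given by chromosome, start and end in rn4, without gene, exon or intron annotation.

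Where each protein was enriched was asked first. At equal depth, 435 regions were enriched for Hdac3 in OPCs, 445 for Hdac3 at d3, 382 for p300 in OPCs and 325 for p300 at d3. The order of these counts depended on the setting: with the genome mean as the only background they were 1237, 1614, 2101 and 2558, so that p300 had more regions than Hdac3 and more at d3 than in OPCs, and at a Poisson level of 1e-08 they were 208, 173, 153 and 138, with fewer for Hdac3 at d3 than in OPCs. The regions were short, since 94.3%, 94.6%, 95.3% and 94.5% of them spanned a single 1 kb bin, and they held 0.337%, 0.300%, 0.257% and 0.235% of the tags of their libraries. The highest enrichment for Hdac3 was on chromosome 13 at 36740001 to 36741000, 75.5-fold over the local background in OPCs and 82.1-fold at d3. The same region was 29.6-fold enriched for p300 in OPCs and 31.6-fold at d3. For p300 in OPCs the highest value was 63.9-fold, on chromosome 1 at 229841001 to 229842000. For p300 at d3 it was 60-fold, on chromosome 2 at 156716001 to 156717000, where Hdac3 was 33.7-fold enriched in OPCs and 48.6-fold at d3. A region on chromosome 13 at 30744001 to 30745000 had the highest mean over the 4 libraries, 55.9-fold.

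Regions with the highest enrichment were common to both proteins and both stages. The 5 regions with the highest fold in each library amounted to 12 distinct regions, and all 12 were called in all 4 libraries. Among them were chromosome 14 at 28434001 to 28435000, with 62.1-fold and 41.3-fold enrichment for Hdac3 in OPCs and at d3, and chromosome 5 at 2704001 to 2705000, with 66.1-fold and 54.4-fold. Chromosome X at 8363001 to 8364000 was 56.9-fold enriched for p300 in OPCs and 38.7-fold at d3. Each aligned read carried a score between 8 and 100 that was read as a mapping quality, with a mean of 84.4 to 88.2 in the 4 libraries. In 11 of the 12 regions the mean score was under 80, with a lowest value of 25.9. The exception was chromosome 5 at 114470001 to 114471000, with a mean score of 88.5 and enrichment of 31.3-fold and 47.4-fold for Hdac3 and of 22.6-fold and 22.5-fold for p300 in OPCs and at d3.

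Over the 4 libraries, 976 regions were called at least once. Of these, 678 were called in 1 library (69.5%, exact binomial interval 66.5 to 72.3%), 115 in 2, 53 in 3 and 130 in 4 (13.3%, 11.2 to 15.6%). The mean read score was at least 80 in 378 of the 678 regions called in 1 library, but in 8 of the 130 called in all 4. A minimum mean score of 80 in the calling library, a limit chosen after the scores had been seen, gave 45 regions for Hdac3 in OPCs, 180 for Hdac3 at d3, 122 for p300 in OPCs and 104 for p300 at d3. These are called well-placed regions below. Bins of such scores called at equal depth without moving the tags had a median offset between strands of 120 bp (95 to 146) for Hdac3 at d3, 53.0 bp (15.5 to 76.0) for Hdac3 in OPCs, 44.5 bp (24.5 to 93) for p300 in OPCs and 65.2 bp (-7.75 to 102) for p300 at d3. Of the 180 for Hdac3 at d3, 163 were called in no other library, and the same held for 28 of the 45 for Hdac3 in OPCs, 102 of the 122 for p300 in OPCs and 81 of the 104 for p300 at d3.

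**Figure D1:**
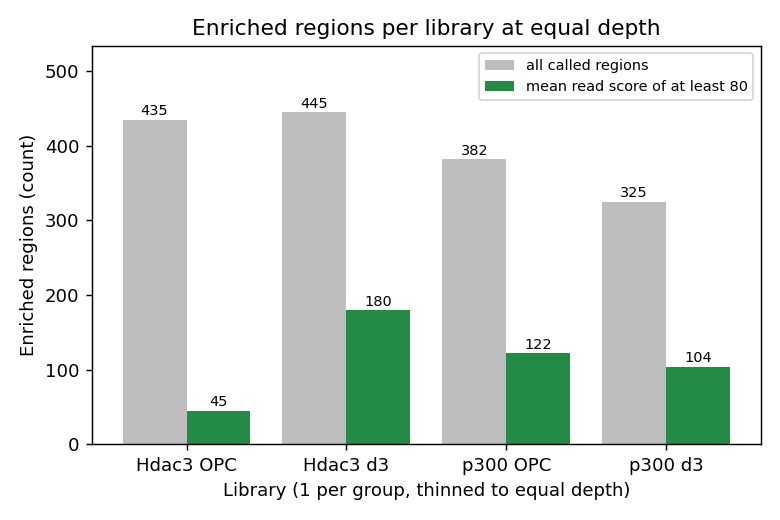
Number of enriched regions (vertical axis) in each library (horizontal axis) after thinning to 3488532 tags, for all called regions (grey) and for those with a mean read score of at least 80 (green), with no error bars because each group held 1 library. All called regions range from 325 to 445, whereas well-placed regions range from 45 for Hdac3 in OPCs to 180 for Hdac3 at d3.

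**Figure D2:**
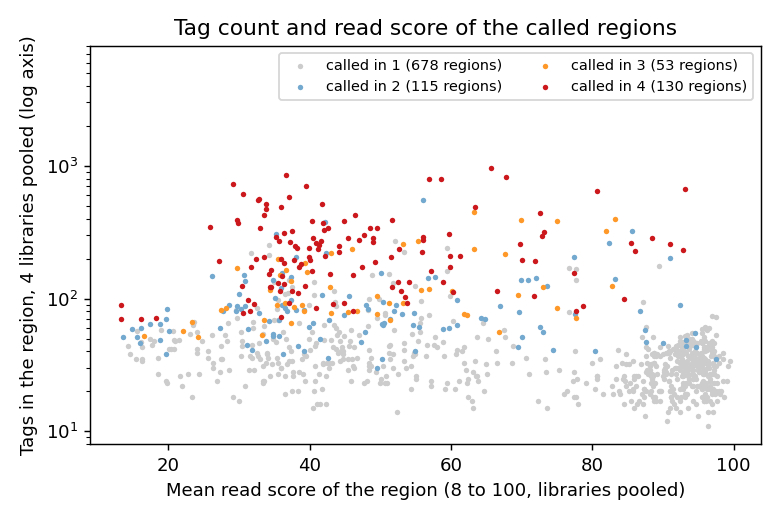
Tags per region summed over the 4 libraries (vertical log axis) against the mean read score of the region (horizontal axis, 8 to 100), 1 point per called region, coloured by the number of libraries in which it was called. The 130 regions called in 4 libraries lie mostly at low scores and high tag counts, and 8 of them have a mean score of at least 80.

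Hdac3 occupancy at d3 was compared with that in OPCs, the comparison named by the design. Among 664 regions called at either stage, 87 had more Hdac3 tags, scaled to depth as RPM, at d3 and 124 had fewer, judged by whether the interval of the ratio excluded 1. Counting error alone would give at most 16.6 in each direction. That value leaves out spread beyond counting error and the bias from picking regions by a call at either stage. The median log2 ratio of d3 to OPC was -0.22 (-0.30 to -0.15). Among the 234 regions with at least 50 tags, 8 were higher and 46 lower, with a median of -0.24. The median stayed below 0 with 500 bp bins (-0.30), at a Poisson level of 1e-08 (-0.28), without bins high in every library (-0.17), with the second thinning seed (-0.24) and against the genome mean (-0.058). It was not below 0 with reads of a score of at least 50, where 77 regions were higher and 46 lower and the median was 0.063 (-0.023 to 0.304). Without thinning it was 0.62, but most regions were then picked by a call in the deeper d3 library (1313 against 512 in OPCs), which favours higher values at d3. With thinning the bias runs the other way. Calls then used 3488532 of 4337338 OPC tags but 3488532 of 8916784 d3 tags, while ratios used all tags, which favours lower values at d3. Every setting listed with a median below 0 kept the thinning, so the sign of the change is not settled. The count of well-placed regions was 4 times as high at d3 as in OPCs (2.87 to 5.68) at the minimum mean score of 80, 2.11 times (1.67 to 2.68) at a minimum of 60 and 6.8 times (4.23 to 11.5) at 90. Of the 214 well-placed regions of either stage 80 were higher and 21 lower at d3, with a median log2 ratio of 1.11, but since most of them were chosen by their d3 call this restates the difference in counts and is no separate measure of direction.

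The largest increases of Hdac3 among regions with at least 50 tags were on chromosome 19 at 10083001 to 10084000, with 1.84 RPM in OPCs and 5.94 at d3 (ratio 3.22, 1.52 to 7.85), and on chromosome 3 at 95698001 to 95699000, with 2.31 and 5.16 (2.24, 1.11 to 4.97). Their mean scores were 96.9 and 97.5. The next were chromosome 2 at 115539001 to 115540000 (ratio 1.92, 1.21 to 3.19), chromosome X at 129361001 to 129363000 (1.86, 1.08 to 3.38) and chromosome 8 at 120171001 to 120172000 (1.79, 1.38 to 2.37), with mean scores of 34.5, 73.1 and 72.5. The largest decrease was on chromosome 2 at 145713001 to 145714000, from 15.0 to 4.37 RPM (ratio 0.292, 0.191 to 0.441). Decreases followed on chromosome 15 at 63805001 to 63806000 (0.450, 0.251 to 0.806), chromosome X at 95071001 to 95072000 (0.486, 0.300 to 0.789), chromosome 16 at 21597001 to 21599000 (0.504, 0.289 to 0.879) and chromosome 4 at 45795001 to 45796000 (0.517, 0.309 to 0.865). Mean scores in these 5 regions lay between 32.6 and 53.1.

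Regions seen at d3 alone were also described for the well-placed set, by a rule set after the data had been seen: the 5 of highest fold called in that library and no other. That choice itself favours a high ratio to the other stage and few tags elsewhere, so the intervals of these ratios describe the regions and do not test them. For Hdac3 at d3 the first was chromosome 3 at 100431001 to 100432000, with 42 tags at d3 against 2 in OPCs (ratio 10.2, 2.66 to 87.1) and 2 tags in each p300 library. Chromosome 2 at 108040001 to 108041000 held 36 tags at d3 and 1 in each other library (ratio 17.5, 2.95 to 711). Chromosome 16 at 84208001 to 84209000 held 27 tags against 2 in OPCs, and chromosome 15 at 36739001 to 36740000 held 38 against 4. The remaining region, on chromosome 19 at 10083001 to 10084000, was the one with the largest increase above. For Hdac3 in OPCs the first 5 regions held 11 or 12 tags each, and the OPC to d3 ratios ran from 1.76 (0.745 to 4.10) on chromosome 1 at 75811001 to 75812000, the first by fold, to 7.54 (1.99 to 42.1) on chromosome 8 at 55012001 to 55013000. The interval also included 1 on chromosome 3 at 141758001 to 141759000 (2.06, 0.808 to 5.23).

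**Figure D3:**
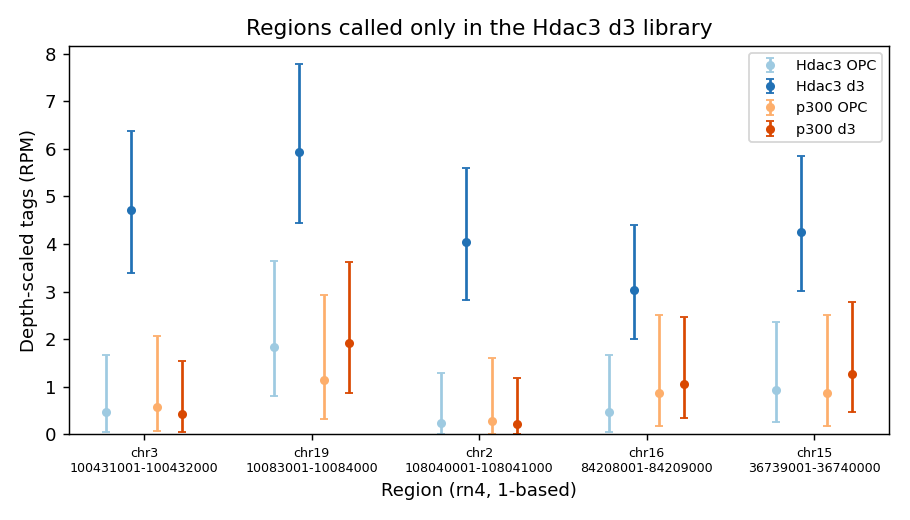
Depth-scaled tags in RPM (vertical axis) in the 4 libraries at the 5 well-placed regions of highest fold that were called for Hdac3 at d3 and in no other library (horizontal axis, rn4 coordinates), with exact 95% Poisson intervals for counting error as bars. Hdac3 at d3 lies between 3.03 and 5.94 RPM, and the other libraries lie between 0.212 and 1.91.

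Occupancy by p300 was compared between the stages in the same way. Of 535 regions called at either stage, 47 had more p300 tags by RPM at d3 and 81 had fewer. Counting error alone would give at most 13.4 in each direction, again leaving out other spread and the bias from picking regions by a call. Calls used all 3488532 OPC tags but 3488532 of 4712200 d3 tags, while ratios used all tags, which favours lower values at d3. The median log2 ratio was -0.20 (-0.28 to -0.10). Among the 123 regions with at least 50 tags the decrease was not seen, as 10 were higher and 8 lower with a median of -0.015, and without thinning the median over all regions was -0.038 (-0.158 to 0.047). With reads of a score of at least 50 it was -0.13 (-0.340 to 0.005), and both intervals included 0. The median was further below 0 without bins high in every library (-0.43, -0.54 to -0.27, with 42 regions higher and 77 lower) and was -0.25 with 500 bp bins (38 and 97). Both stages called 172 of the regions, OPCs alone 210 and d3 alone 153. In the well-placed set 33 of 212 regions were higher and 52 lower with a median of -0.35 (-0.685 to 0.024), and the number of such regions at d3 was 0.852 times that in OPCs (0.650 to 1.12), a difference within counting error. Against the genome mean alone as background the median log2 ratio turned to 0.20.

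The largest increase of p300 among regions with at least 50 tags was on chromosome 1 at 262032001 to 262033000, from 2.29 to 11.9 RPM (ratio 5.18, 2.46 to 12.6), with a mean score of 76.7. It was followed by chromosome 18 at 24374001 to 24375000 (1.94, 1.5 to 2.54), chromosome 3 at 8833001 to 8835000 (1.83, 1.43 to 2.36) and chromosome 16 at 28013001 to 28015000 (1.81, 1.06 to 3.22). For chromosome 2 at 115539001 to 115540000 the ratio was 1.78, with an interval of 0.949 to 3.49 that included 1. The largest decreases were on chromosome 1 at 16019001 to 16020000 (0.420, 0.234 to 0.737), chromosome 3 at 10197001 to 10198000 (0.423, 0.231 to 0.753), chromosome 14 at 4669001 to 4670000 (0.518, 0.282 to 0.936) and chromosome 16 at 59044001 to 59045000 (0.571, 0.332 to 0.971). For chromosome 14 at 4510001 to 4511000 the ratio of 0.582 (0.317 to 1.05) was within counting error. Mean scores in these 10 regions were all under 80. Among the 5 well-placed p300 regions of highest fold called in OPCs alone, picked in the same way, the OPC to d3 ratio ran from 1.89 (0.781 to 4.76) on chromosome 5 at 159442001 to 159443000, the first by fold, to 4.73 (1.48 to 19.7) on chromosome 1 at 163689001 to 163690000. Among the 5 called for p300 at d3 alone, the d3 to OPC ratio ran from 2.59 (0.814 to 10.8) on chromosome 1 at 162341001 to 162342000, the first by fold, to 9.62 (1.45 to 409) on chromosome 4 at 152319001 to 152320000, and its interval also excluded 1 on chromosome 2 at 177683001 to 177684000 (3.15, 1.03 to 12.9).

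Whether Hdac3 and p300 occupied the same places, the subject of the series title, was examined at each stage. In OPCs 170 of 382 p300 regions overlapped an Hdac3 region (44.5%, 39.4 to 49.6%). At d3 the overlap was 153 of 325 (47.1%, 41.5 to 52.7%). These shares were 72.5% and 73.9% at a Poisson level of 1e-08 and were 20.6% and 21.9% without bins high in every library. Random placement of the p300 regions on their chromosomes gave a mean of 0.09 overlaps in OPCs and 0.12 at d3. At each stage 128 of the overlapping regions were those called in all 4 libraries. Among well-placed regions the overlap was 7 of 122 in OPCs (5.74%, 2.34 to 11.5%) and 10 of 104 at d3 (9.62%, 4.71 to 17.0%), against a random mean of 0.01 at either stage. Random placement does not account for sites that collect reads in any library, so overlap above it does not by itself show joint binding. The overlaps in OPCs and at d3 had intervals that covered each other, for all regions and for well-placed ones.

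Well-placed regions were also compared by the tags of the libraries that did not call them. At the 168 well-placed Hdac3 d3 regions not called for Hdac3 in OPCs, Hdac3 tags in OPCs were 2.04-fold over the local background (1.80 to 2.25, bootstrap over regions). For p300 the values at regions not called in the library concerned were 2.41-fold in OPCs (2.16 to 2.66) and 2.21-fold at d3 (2.04 to 2.41). Random bins chosen for a mean score of at least 80 in the Hdac3 d3 library gave 1.10-fold, 1.11-fold and 1.12-fold. At the 114 well-placed p300 regions of OPCs not called for Hdac3 there, Hdac3 tags were 2.15-fold over background (1.83 to 2.47).

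Changes of the proteins from OPC to d3 were set against each other region by region. Over the 976 regions the log2 ratios of Hdac3 and p300 showed no detectable correlation (Pearson r = 0.00058, -0.062 to 0.063, and Spearman rho = -0.013), where regions are not independent replicates. Of these regions 678 were called in 1 library. Counting noise at low tag counts pulls r toward 0, so a relation is not excluded. Over the 130 regions called in all 4 libraries, of which 8 had a mean score of at least 80, r was 0.265 (0.097 to 0.418). Over the other 846 it was -0.0020. Over the 130 regions with at least 50 tags for each protein r was 0.289 (0.123 to 0.439), and over 5059 windows of 500 kb on the autosomes it was 0.151. Of the regions in which both ratios had intervals that excluded 1, 2 were higher at d3 for both proteins, 5 were lower for both and 5 moved in opposite directions. Higher for both was chromosome 7 at 101749001 to 101751000, with ratios of 1.37 (1.12 to 1.68) for Hdac3 and 1.43 (1.02 to 2.01) for p300. In the opposite group, chromosome 3 at 95698001 to 95699000 rose for Hdac3 (ratio 2.24) and fell for p300 (0.308, 0.085 to 0.941), while chromosome 18 at 24374001 to 24375000 fell for Hdac3 (0.522, 0.333 to 0.819) and rose for p300 (1.94). These last regions were picked out after their values had been seen, apart from those among the largest changes.

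Chromosome X carried 4.01% of Hdac3 reads in OPCs and 4.04% at d3, but 3.55% of p300 reads in OPCs (3.53 to 3.57%) and 3.02% at d3 (3.003 to 3.034%). In 5 Mb windows of X the median log2 ratio of d3 to OPC, relative to the autosomes, was -0.27 for p300 and 0.02 for Hdac3.

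**Figure D4:**
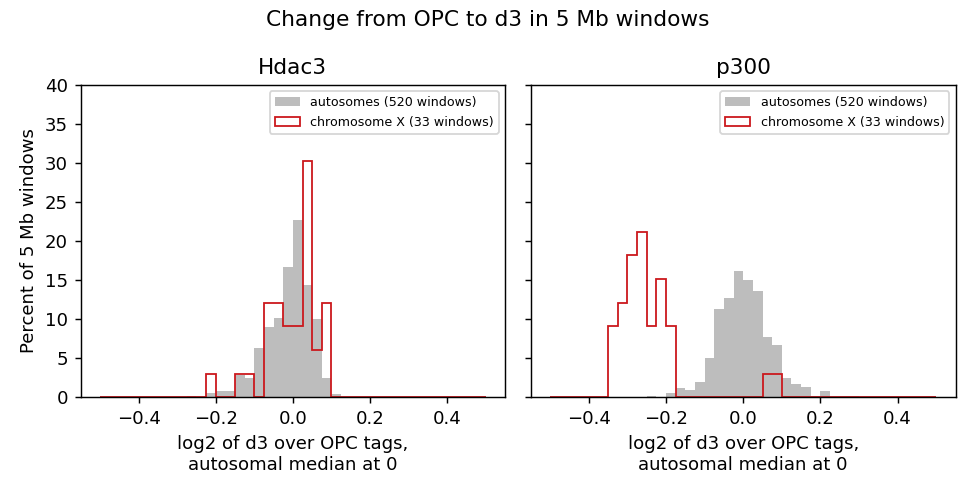
Distribution of the log2 ratio of d3 to OPC tags (horizontal axis, autosomal median at 0) in 5 Mb windows as a percent of windows (vertical axis), for 520 autosomal windows (grey) and 33 windows of chromosome X (red), with Hdac3 at left and p300 at right. For p300 the X windows lie below the autosomes with a median of -0.27, whereas for Hdac3 the median of X is 0.02.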

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

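The tests of the chromosome X pattern were chosen after the X shares had been seen, but their bounds were set before the windows were examined. The share of reads on chromosome X differed between the proteins in its change from OPC to d3: it fell by 0.528 percentage points for p300 and rose by 0.037 for Hdac3. With 1 library per group this difference between the proteins was not tested.

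The lower X share of p300 at d3 spread over the chromosome, since 31 of 33 windows of 5 Mb on X (93.9%, exact binomial interval 79.8 to 99.3%) lay below the autosomal median, and none of the 520 autosomal windows lay below the X median of -0.27. A shift of p300 tags between broad domains that follows their p300 to Hdac3 ratio in OPCs is argued against. The autosomal relation between that ratio and the change of p300 predicted 3.86% of the drop on X (bootstrap -0.12 to 7.26%), under the 25% set as its lower bound. Shifts along other features of the domains were not tested. A different mix of female and male pups in the preparations remains a candidate explanation for the drop along most of X. Alone it would also have lowered the pair of adjacent exceptions from 125000001 to 135000000 (0.064 and 0.085), if all reads placed there came from X. Examined after these exceptions had been seen, 3 windows of 1 Mb from 128000001 to 131000000 rose and the other 7 fell. Those 3 held 1.18, 1.41 and 1.53 times the autosomal median density for Hdac3 in OPCs, against 0.677 and 0.487 in the windows on either side. In every library they lay above both neighbours. Whether they report the copy number of X was not tested, so they do not decide the question. Elsewhere on X, 1 window of 1 Mb rose, from 124000001 to 125000000 (0.118). The Hdac3 libraries, with X densities of 0.665 and 0.671 of the autosomal level against 0.585 and 0.495 for p300, did not show the drop. A different mix of pups would therefore also need the antibodies to have been used on different preparations, which the labels do not say. A loss of p300 from X during differentiation stays open and untested. The X share counts all tags, of which called regions held 0.257% for p300 in OPCs and 0.235% at d3. It is therefore no measure of p300 at called regions.

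Reads on the mitochondrial chromosome, which entered no comparison, made up 0.525% of reads for Hdac3 in OPCs, 0.175% for Hdac3 at d3, 0.569% for p300 in OPCs and 0.383% for p300 at d3.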

How the results depend on the processing

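The second thinning seed, the score limits and the genome mean as the only background were chosen after the data had been seen. Of 143 values under 11 alternatives, 92 stayed within their bounds, 47 moved and 4 changed sign. Of the 92, 26 could not move and are no evidence of stability: all tags kept, since no 5' end was repeated on a strand, and overlap of 50% of the shorter region, since regions of 1 or 2 bins on a shared grid always overlap by that much. Of the values of the other 9 alternatives 66 stayed within their bounds, among them those for the second seed and for scaling by tags outside regions. That scaling cannot move counts of called regions, overlaps or the correlation. The smallest library, p300 in OPCs, lost no tags in thinning, so its count of regions could not move with the second seed or without thinning. The cause of the shifts was not tested except where stated. No paired analysis was possible because each group held 1 library. Promoter, gene list, signal and peak list alternatives were not run, since gene positions in rn4 were not used here and the files hold reads. Depth limits the calls, as simulated 5-fold sites were recovered in 10% to 28% of cases.

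Values in each list follow the order Hdac3 OPC, Hdac3 d3, p300 OPC, p300 d3. With 500 bp bins the Hdac3 median log2 ratio was -0.30. At a Poisson level of 1e-08, 208, 173, 153 and 138 regions were called, with 15 higher and 58 lower at d3 for Hdac3, 10 and 16 for p300, and overlaps of 72.5% in OPCs and 73.9% at d3. Without thinning, Hdac3 at d3 had 1313 regions, 316 regions were higher at d3 for Hdac3, its median changed sign to 0.62, the p300 median was -0.038 and overlaps were 50% and 58.4%. Leaving out bins over 10 times the mean in every library gave 252 and 192 p300 regions, a p300 median of -0.43 and overlaps of 20.6% and 21.9%, by removing shared bins.

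Reads with a score of at least 50 gave 201 regions for Hdac3 in OPCs, 230 and 203 for p300, 77 Hdac3 regions higher and 46 lower at d3, which turns the order of 87 and 124, an Hdac3 median of 0.063 (-0.023 to 0.304), and an OPC overlap of 36.1%. With the genome mean alone there were 1237, 1614, 2101 and 2558 regions, 269 higher and 327 lower for Hdac3 with a median of -0.058, 464 and 489 for p300 with a median that changed sign to 0.20, and overlaps of 28.1% and 22.4%. A mean score of at least 80 gave 45, 180, 122 and 104 regions, 21 lower at d3 for Hdac3 with a median that changed sign to 1.11, 52 lower for p300 with a median of -0.35 (-0.685 to 0.024), overlaps of 5.74% and 9.62%, and a correlation of 0.066. The 4-fold count of well-placed Hdac3 regions at d3 was 4.55-fold with the second seed, 2.11-fold (228 and 108) at a minimum mean score of 60 and 6.8-fold (136 and 20) at 90.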

Other observations

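The tests of the well-placed regions and the broad windows were chosen after these results had been seen, while the bounds for the strand offsets of shared regions were set before the offsets were computed. Over windows of 500 kb on the autosomes, libraries of different antibodies differed more than libraries of the same antibody at different stages. With 1 library per group and no input, an effect of the antibody cannot be told apart from one of preparation or library. The variance between libraries at equal depth was 8.93 times the Poisson value for Hdac3 against p300 in OPCs and 11.1 times at d3, but 1.99 times between the stages for Hdac3 and 3.03 times for p300. The log2 ratio of p300 to Hdac3 per window in OPCs followed that at d3 (Pearson r = 0.812, Spearman rho = 0.842 over 5059 windows, which are not replicates), with no library in common. In 300 windows p300 was over 1.2-fold higher than Hdac3 at both stages, and in 731 windows Hdac3 was higher by that fold. Windows with most p300 included chromosome 7 at 22500001 to 23000000, where the ratio of p300 to Hdac3 was 1.58 in OPCs and 1.69 at d3, and chromosome 16 at 1000001 to 1500000, with 1.63 and 1.56. Windows with least p300 included chromosome 1 at 75000001 to 75500000 (0.445 and 0.529) and chromosome 5 at 134000001 to 134500000 (0.608 and 0.567).

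Single regions also differed between the antibodies. Tags were scaled to depth, and a region counted only where the interval of the ratio of Hdac3 to p300 excluded equal amounts. By this rule 43 of 976 regions held more Hdac3 than p300 tags at both stages, against 21.3 for independent stages. Another 29 regions held more p300 tags at both stages, against 12.8 for independent stages. Both values for independent stages take every region as equally likely to pass. Regions with more tags pass more easily, so the excess does not by itself show a lasting difference between the antibodies. An example with more p300 tags is chromosome 3 at 8833001 to 8835000, with 26.1 RPM for p300 and 7.84 RPM for Hdac3 in OPCs and 47.7 and 4.71 at d3.

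Regions with the highest tag counts, called in all 4 libraries, had plus and minus strand tags displaced by a median of 30.0 bp (24.0 to 34.0), close to the read length, and a median score of 41.8 against a genome mean of 86.6. This argues against Hdac3 and p300 both bound there as the source of these counts, since a bound site was taken to give an offset of at least 80 bp. The 678 regions called in 1 library were also below that bound as a whole, at 52.0 bp (35.5 to 64.5), with 114 bp (87.5 to 137) for the 378 of a mean score of at least 80 and 29.0 bp (28.0 to 30.5) for the other 300, where calling after moving the tags favours larger offsets. Reads collapsed onto 1 copy of repeats, or onto sequence with copies missing from the assembly, are a candidate explanation and predict both values, and the 43 regions with more Hdac3 and the 29 with more p300 also had median offsets of 30.0 bp (28.0 to 32.5 and 28.0 to 94.0) and median scores of 49.2 and 72.1. Collapsed reads do not say why the antibodies differ, and binding within repeats stays open, because no input library was used here.

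More well-placed Hdac3 regions at d3 than in OPCs may reflect a gain of Hdac3 sites during differentiation, a hypothesis that these libraries cannot test. The 4-fold count (2.87 to 5.68, above the bound of 1.5) was itself taken at equal depth. The number of tags used for calling is therefore argued against as its source. The mean scores used all tags of each library, and whether depth acted through the score limit was not tested. Chance clusters of tags are argued against at d3, since the 153 bins of high score called at equal depth without moving the tags had a median strand offset of 120 bp (95 to 146), and the 722 called at full depth 108 bp (93.7 to 122). The same measure at equal depth did not clear the 80 bp bound for Hdac3 in OPCs (53.0 bp, 15.5 to 76.0), p300 in OPCs (44.5 bp, 24.5 to 93) or p300 at d3 (65.2 bp, -7.75 to 102), so part of the well-placed regions of those libraries could be chance. At full depth it was 17.5 bp (-46 to 58.5) for Hdac3 in OPCs and 71.75 bp (16 to 120) for p300 at d3. Without a score limit, Hdac3 had 435 regions in OPCs and 445 at d3 at equal depth, so the 4-fold count rests on that limit. The mean score was 84.4 for Hdac3 in OPCs and 86.2 at d3. Whether this difference in scores accounts for the count was not tested. A lower pull-down yield in the Hdac3 OPC library cannot be told apart from a biological gain: Hdac3 tags in OPCs were 3.18-fold over background at the 180 regions of Hdac3 at d3 (2.48 to 4.06), above random bins, with an interval that overlapped that of p300 in OPCs (3.11, 2.65 to 3.60), and at the 168 that each of these OPC libraries did not call the values were 2.04-fold (1.80 to 2.25) and 2.41-fold (2.16 to 2.66).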
